A study of Sus scrofa with 37 samples.

How the data were processed

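RNA from flash-frozen skeletal muscle of Bama minipigs was extracted with Trizol, its integrity was measured on a Bioanalyzer, and libraries made with the NEBNext Ultra RNA kit were read as 150 bp pairs on a HiSeq-2500, per the labels' protocols. FastQC, MultiQC, Trimmomatic, HISAT2 2.2.1, HTSeq and the genome build Sscrofa11.1 are named in the submitters' processing notes, which state neither the annotation release nor the strand setting of the counting. The values are raw counts per gene, deposited as 1 table of 9418 rows by gene symbol and 37 columns, all of which were matched to a sample by title. Each row has a largest count of at least 101, so the table is a selected part of each library. The rule of selection is not given in the sources used here, and column totals (9.86 to 22.9 M) are not the sequencing depth. Without a stated strand setting, reads of overlapping antisense genes could not be told apart, and genes with near-identical copies (AMCF-II, MT1A, HBB, FTL, H1-4, TUBB and ribosomal proteins) are uncertain. A floor of 3 counts lay between 0.108 and 0.378 CPM over the libraries, for counting error only.

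Libraries were grouped by their titles into control (9) and the 7 times (4 each). The replicate numbers gave no clear sign of pairing libraries across times, though pairing is not excluded. Libraries in a group were compared pairwise by a chi-square of their counts over genes with at least 20 counts in sum, and no pair was as alike as sampling noise, the lowest chi-square per degree of freedom being 16.1.

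In R 4.3.3, edgeR 4.0.16 with limma 3.58.1 normalized the counts by TMM, kept 9411 genes with filterByExpr and fitted quasi-likelihood models with robust dispersion to all 37 libraries with the group as the only factor. Tests were each time against control, the 7 times together, the 6 successive pairs and, in the 28 injured libraries, a slope on log2 hours. P-values were adjusted by Benjamini-Hochberg over genes with a threshold of 0.05. Fold changes of at least 2 are those with an absolute log2 change of at least 1. Camera tested 38 gene lists, with a preset correlation of 0.01 between genes, adjusted over the lists of all comparisons of a kind, and again with a correlation estimated in each list. The lists were immediate early genes, cytokines, endothelial activation, markers of neutrophils, macrophages, lymphocytes, mast cells, erythrocytes and platelets, endothelial cells, pericytes, fibroblasts, adipocytes, Schwann cells and keratinocytes, matrix, contractile, slow fibre, fast fibre and calcium genes, nuclear and mitochondrially encoded respiratory genes, the tricarboxylic acid cycle, glycolysis, fatty acid use, heat shock, unfolded protein, oxidative stress, hypoxia, wasting, myogenic, cell cycle, interferon, class II, complement, clock, glucocorticoid, cell death and ribosomal genes. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. Lists share some members, such as HK2 in glycolysis and hypoxia. Genes were named by rule: at each time the 6 largest rises and 4 largest falls among called genes with at least 5 CPM in the higher group and no overlap with the controls, the 10 smallest p-values among the times, 3 rises and 3 falls for each successive pair, 5 and 5 slopes, and up to 4 members of each list by smallest p. Genes named as changed at all 7 times are from these rules. Some genes that the rule picked are not reported here. Gene coordinates are spans in Sscrofa11.1 from a gene table that held 8945 of the 9411 symbols.

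Alternatives fixed beforehand were other size factors, other filters, DESeq2 1.42.0, limma-voom, a replicate block, fewer libraries in the fit, a test against 2-fold, other time scales, fry and leaving out each library. After the data were examined, 5 library sets were defined from column totals (above 20 M), C1QBP (above 8 CPM), NDUFAF8 (below 4 CPM) and ND6 (at most or above 32 CPM), applied in that order. The genes came from a search over all genes for wide gaps between libraries, the thresholds were placed by eye, and the 5 sets were fitted as a term first. A version with 4 sets, without the ND6 split, was added after its calls were seen because only ND6 parted sets 4 and 5. As the sets come from expression values, calls of C1QBP, NDUFAF8 and ND6 for a set are circular, and C1QBP, ND6 and the like-behaving MRPL57 and TMEM238 are among the named genes. Controls of the same set, scaling by column totals, the fit without 48 h replicates 2 and 4 and the fit without the 8 libraries of set 2 were also added then. Scaling by totals shifted the median log2 change of all genes by -0.15 at 4 h, 0.35 at 16 h, 0.33 at 20 h, 0.48 at 24 h, 0.36 at 48 h, 0.37 from 12 to 16 h, 0.15 from 20 to 24 h and -0.12 from 24 to 48 h, so directions are relative to the TMM scale.

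The fits were tested on simulated counts with 200 changed genes. At 48 h against control, 67% of genes changed by a log2 of 1 and 98% of those changed by 2 were recovered, with 6 unchanged genes among 171 calls over 9351 genes. From 24 to 48 h 58% and 95% were recovered, and among the 7 times 52% and 97%. Lists raised in the simulation at 48 h were called in 20 (cell cycle), 15 (neutrophil) and 20 (hypoxia) of 20 draws with the preset correlation and in 20, 11 and 20 with an estimated one.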

Results

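Gene expression in skeletal muscle of Bama minipigs, a miniature pig breed, was measured by RNA sequencing after contusion, a blunt mechanical injury. The design text gives 8 minipigs and 4 biological replicates at each of 7 times between 4 and 48 h after injury. A further 9 libraries are labelled as controls. The labels give mechanical damage as the treatment of every library, controls included, so how the control muscle was handled is not given in the sources used here. The table holds raw counts of part of each library, without genes low in every library, and 9411 genes were tested. Column totals ran from 9.86 to 22.88 M counts, with 10.3 to 12.3 M in the controls, 10.9 to 21.5 M at 4 h, 12.3 to 13.5 M at 16 h and 9.91 to 22.88 M at 24 h. No pair of libraries in a group agreed within sampling noise. The 37 libraries came from 8 animals and the labels do not say which libraries share one. Every p-value below therefore measures only spread between libraries and says nothing about animals.

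Values after ± are standard errors for log2 fold changes and standard deviations (n = 4 libraries per time, n = 9 controls) for CPM, counts per M after TMM scaling. Every gene picked for its fold change at a time had all 4 injured libraries on one side of all 9 controls. In the controls 3 counts in a library corresponded to 0.236 to 0.369 CPM, so fold changes of genes near or below that level there rest on few counts. Of 38 gene lists fixed beforehand, those named are given with the members called over all genes tested first. Members called when adjusted over the list alone follow if different, marked alone. The median log2 change of the members tested and the p-value of the list by camera come last. No list call held with a correlation estimated in each list. A list was called as a whole, also where few members passed.

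The libraries also split on something other than time. After the data were examined, a search over all genes for wide gaps between libraries found C1QBP, which encodes a mitochondrial matrix protein, with a lowest value of 9.35 CPM in 9 libraries and a highest of 3.04 CPM in the others. NDUFAF8, which encodes an assembly factor of respiratory complex I, had a highest value of 2.27 CPM in 8 libraries and a lowest of 8.80 CPM in the rest. ND6, the complex I subunit encoded on the light strand of mitochondrial DNA, was at most 13.8 CPM in 8 of the remaining libraries and at least 57.9 CPM in 9. Column totals were above 21.5 M in 3 libraries and at most 13.5 M in the others. Thresholds placed by eye in these gaps gave 5 library sets, which no label names. Set 1 held 2 controls, 3 libraries at 8 h and all 4 at 16 h. Set 2, low in NDUFAF8, held 3 libraries at 4 h, 2 at 12 h, 2 at 20 h and 1 at 24 h. Set 3, with the large totals, held 1 library at 4 h and 2 at 24 h. Set 4, low in ND6, held 4 controls, 2 libraries at 12 h and 2 at 20 h, and set 5 held 3 controls, 1 library at 8 h, 1 at 24 h and all 4 at 48 h. No control was in set 2 or set 3, so the 4 h libraries have no control of their own set. In models with time and set, edgeR called 304 genes for set 2 against set 5 (296 lower), 65 for set 1, 9 for set 3 and 1 for set 4, the last being ND6 itself. The fits below leave the sets out, as fixed beforehand, and values with the sets as a term, or against controls of the same set, stand beside them.

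**Figure D1:**
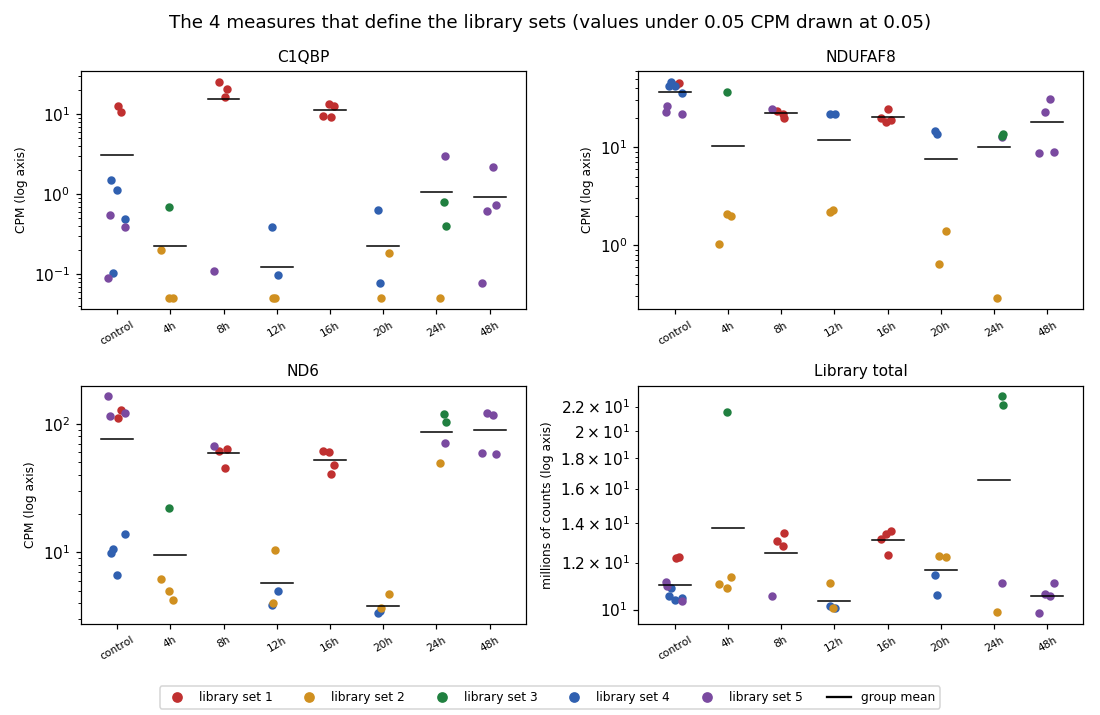
Levels of C1QBP, NDUFAF8 and ND6 (CPM, log axis; values under 0.05 CPM drawn at 0.05) and the library total (M counts) in each of the 37 libraries by group, coloured by library set. The lowest C1QBP of the 4 libraries at 16 h is 9.35 CPM and the highest of those at 12 h 0.39 CPM.

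At 4 h, CCL2, the chemokine that attracts monocytes (chromosome 12, 40798109 to 40800013), rose (log2 fold change 4.28 ± 0.66 (SE), 185 ± 178 CPM (SD, n = 4) against 9.45 ± 7.63 CPM (SD, n = 9), edgeR adjusted p = 6.61e-05). FOSL1, a subunit of the AP-1 transcription factor (chromosome 2, 6430158 to 6436173), rose by 4.17 ± 0.55 on the log2 scale. LOXL4, a lysyl oxidase-like enzyme that cross-links matrix proteins (chromosome 14, 109571942 to 109593408), rose by 3.84 ± 0.46. SOX9, a transcription factor of cartilage formation, rose by 3.53 ± 0.55, and RASGEF1A, a Ras exchange factor at 0.336 ± 0.198 CPM in the controls, by 3.95 ± 0.60. NRN1, which encodes neuritin, rose from 1.13 ± 1.72 to 12.2 ± 4.84 CPM. The transcription factor gene BARX2 fell from 7.83 ± 11.7 to 0.404 ± 0.12 CPM (-4.25 ± 0.97). TBX1 (-3.06 ± 0.46), the tubulin-binding TPPP (-3.67 ± 0.73) and the endosomal ZFYVE28 (-2.56 ± 0.41) fell too.

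Fast fibre genes (5 of 13 higher, 6 higher alone, median 1.34, camera adjusted p = 3.54e-05) and glycolysis genes (4 of 23 higher and 1 lower, 9 higher and 1 lower alone, median 1.15, camera adjusted p = 2.79e-05) were higher at 4 h as lists. Neither held (adjusted p = 0.635 with an estimated correlation). Slow fibre genes (5 of 12 lower, 8 lower alone, median -0.98, camera adjusted p = 0.00517) and fatty acid use (1 of 26 higher and 16 lower, 1 higher and 19 lower alone, median -0.89, camera adjusted p = 2.56e-06) were lower. Their calls were lost too (adjusted p = 0.635 to 0.701 with an estimated correlation). Oxidative phosphorylation (4 of 40 lower, 2 lower alone, median -0.33, camera adjusted p = 0.00389) and the tricarboxylic acid cycle (2 of 20 lower, 1 lower alone, median -0.40, camera adjusted p = 0.00336) were lower as well. Both calls were lost (adjusted p = 0.729 to 0.818 with an estimated correlation). Matrix (6 of 30 higher, median 0.27, camera adjusted p = 0.0233) and endothelial activation genes (3 of 13 higher, 5 higher alone, median 0.63, camera adjusted p = 0.0339) were higher. These did not hold (adjusted p = 0.729 with an estimated correlation). TIMP1, an inhibitor of metalloproteinases, rose by 3.29. The unfolded protein and amino acid response (6 of 22 higher, median 0.47, camera adjusted p = 0.00108) and interferon response (5 of 24 higher, median 0.50, camera adjusted p = 9.71e-05) were higher. Neither passed otherwise (adjusted p = 0.635 with an estimated correlation). So were hypoxia (3 of 20 higher and 1 lower, 5 higher and 1 lower alone, median 0.32, camera adjusted p = 0.0208) and cell death genes (3 of 18 higher, 8 higher alone, median 0.65, camera adjusted p = 0.00118), while pericyte and smooth muscle markers were lower (1 of 14 higher and 6 lower, 1 higher and 7 lower alone, median -0.56, camera adjusted p = 0.00684). All 3 lost their calls (adjusted p = 0.635 with an estimated correlation).

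EdgeR's quasi-likelihood test called 1721 of 9411 genes at 4 h (868 higher, 853 lower), 312 higher and 351 lower by at least 2-fold, with libraries that share animals. Scaling by column totals moved the split to 354 higher and 1337 lower. With the 5 sets as a term 259 genes were called, 215 of them shared. NRN1 (edgeR adjusted p = 0.066), BARX2 (0.202), TPPP (0.0958) and the pericyte list (camera adjusted p = 0.187) were no longer among the calls. Without replicate 2, in which SPP1 reached 139 CPM against 7.09 to 22.4 CPM in the other 4 h libraries, 608 genes were called.

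**Figure D2:**
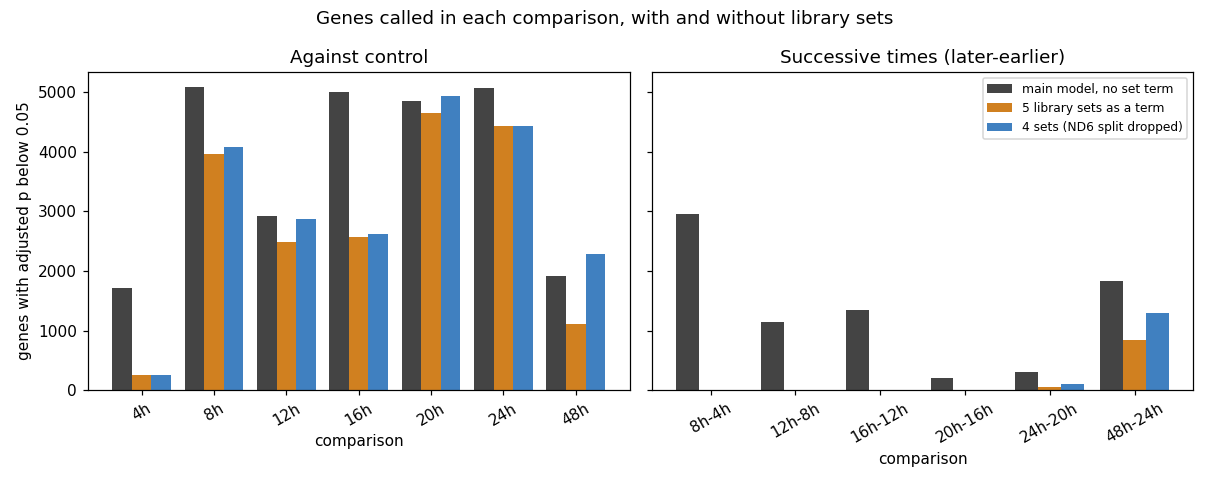
Number of genes called higher or lower at each time against control and between successive times (edgeR, 5% false discovery rate), without library sets and with the 5 sets or 4 sets as a term. Against control the calls without sets run from 1721 to 5084, and with 5 sets the first 4 successive comparisons have none.

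At 8 h, NRG1, a ligand of ErbB receptors (chromosome 15, 52625550 to 53688003), rose (log2 fold change 6.80 ± 0.84 (SE), 13.3 ± 8.24 CPM (SD, n = 4) against 0.106 ± 0.149 CPM (SD, n = 9), edgeR adjusted p = 1.28e-07). CCR1, a chemokine receptor of leukocytes (chromosome 13, 29227218 to 29233862), rose as well (log2 fold change 6.39 ± 0.76 (SE), 116 ± 95.2 CPM (SD, n = 4) against 1.34 ± 1.85 CPM (SD, n = 9), edgeR adjusted p = 8.09e-08). AMCF-II, a pig neutrophil-attracting chemokine (6.71 ± 1.00), and the hyaluronan synthase HAS1 (6.38 ± 0.87) rose. The neuropeptide precursor VGF (6.18 ± 0.88) and the immediate early gene ARC (6.11 ± 0.89) rose too. The control means of these 4 genes were 0.0629 to 0.254 CPM, under 3 counts per library on average. HHIP, an inhibitor of hedgehog signalling (chromosome 8, 83583735 to 83678368), fell from 5.17 ± 2.15 to 0.0486 ± 0.0571 CPM (-6.53 ± 0.69). LGI1, a secreted protein of synapses (-4.71 ± 0.94), the Wnt receptor FZD10 (-4.31 ± 0.76) and the secreted CRISPLD1 (-4.17 ± 0.70) also fell.

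Neutrophil (11 of 11 higher, median 3.81, camera adjusted p = 0.00118) and macrophage markers (16 of 25 higher, median 1.90, camera adjusted p = 0.00389) were higher as lists at 8 h. Their calls were lost (adjusted p = 0.635 to 0.729 with an estimated correlation). IL1R2 rose by 6.09. Endothelial activation (11 of 13 higher, median 1.46, camera adjusted p = 0.0018) and cytokines and chemokines (10 of 18 higher and 2 lower, median 1.07, camera adjusted p = 0.0434) were higher. These were lost too (adjusted p = 0.635 with an estimated correlation). Immediate early (12 of 24 higher and 3 lower, median 0.83, camera adjusted p = 0.0388) and cell death genes (16 of 18 higher and 1 lower, 17 higher and 1 lower alone, median 1.41, camera adjusted p = 5.44e-05) were also higher. Neither kept its call (adjusted p = 0.635 to 0.791 with an estimated correlation). CXCL8 rose by 5.15 and SOCS3 by 5.69. The unfolded protein list (12 of 22 higher and 2 lower, 13 higher and 2 lower alone, median 0.85, camera adjusted p = 0.0032), interferon response (13 of 24 higher, median 0.76, camera adjusted p = 0.00238) and glycolysis (8 of 23 higher and 2 lower, median 0.98, camera adjusted p = 0.0352) were higher. All 3 were lost (adjusted p = 0.635 to 0.771 with an estimated correlation). Oxidative phosphorylation (36 of 40 lower, 39 lower alone, median -0.99, camera adjusted p = 2.02e-08) and fatty acid use (3 of 26 higher and 20 lower, median -1.46, camera adjusted p = 4.94e-05) were lower. Both were lost (adjusted p = 0.635 with an estimated correlation). Slow fibre genes (12 of 12 lower, median -1.78, camera adjusted p = 0.00178), the tricarboxylic acid cycle (11 of 20 lower, median -0.57, camera adjusted p = 0.00255) and mitochondrially encoded genes (10 of 12 lower, median -1.07, camera adjusted p = 0.00272) were lower. None held (adjusted p = 0.652 to 0.729 with an estimated correlation). Pericyte (11 of 14 lower, median -1.34, camera adjusted p = 9.71e-05) and fibroblast markers (1 of 17 higher and 8 lower, median -0.66, camera adjusted p = 0.04998) and ribosomal proteins (7 of 34 lower, 1 lower alone, median -0.27, camera adjusted p = 0.0425) were lower. These fell away as well (adjusted p = 0.635 to 0.873 with an estimated correlation).

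EdgeR called 5084 genes at 8 h (2426 higher, 2658 lower), 1159 and 1167 by at least 2-fold, over libraries that share animals. The 5 sets as a term left 3966 genes called, 3742 of them shared. In the 3 libraries of set 1 against the 2 controls of that set there were 3673. The immediate early (camera adjusted p = 0.262), cytokine (0.114) and ribosomal (0.205) lists passed only without the term, and fibroblast markers (0.102) not against those controls.

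**Figure D3:**
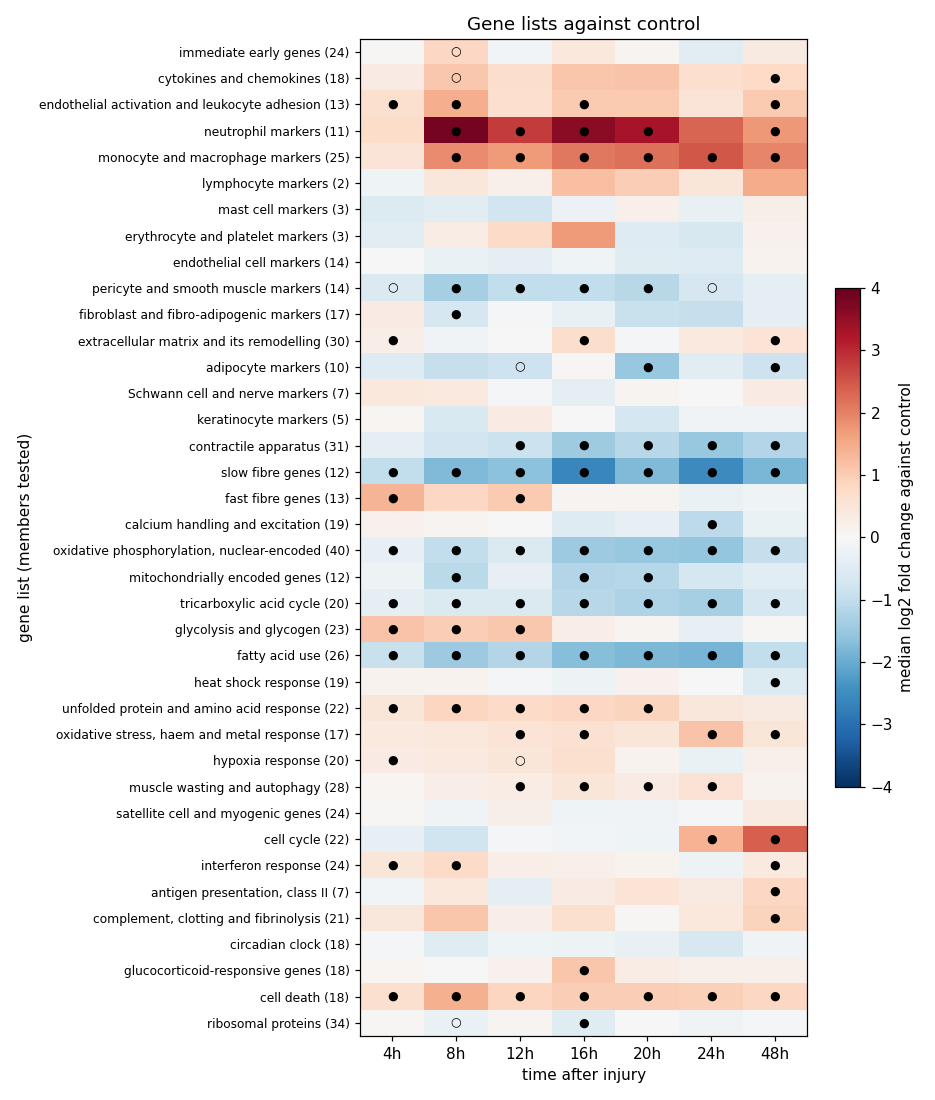
Median log2 change against control of the members of 38 gene lists (number of members tested beside each name) at each of 7 times, red for higher and blue for lower. Filled circles mark lists past 0.05 by camera both without and with the library sets in the same direction, open circles those past it without the sets only.

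At 12 h, LOXL4 rose (log2 fold change 5.32 ± 0.47 (SE), 129 ± 67.2 CPM (SD, n = 4) against 3.19 ± 2.38 CPM (SD, n = 9), edgeR adjusted p = 5.27e-09). TARS3, a threonyl-tRNA synthetase, rose by 5.24 ± 0.58, and TIMP1 (chromosome X, 42103251 to 42106289) by 4.71 ± 0.44 to 296 ± 212 CPM. The membrane protease gene ST14 (4.93 ± 0.61, control 0.194 ± 0.15 CPM) and ARC (4.87 ± 0.91) also rose. ACSM3, a medium-chain acyl-CoA synthetase (chromosome 3, 25247723 to 25284063), fell from 8.82 ± 8.59 to 0.843 ± 0.137 CPM (-3.38 ± 0.63). BARX2 (-4.23 ± 0.98), FZD10 (-3.84 ± 0.74) and TPPP (-3.57 ± 0.73) fell too.

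Neutrophil (8 of 11 higher, 10 higher alone, median 2.79, camera adjusted p = 0.0151) and macrophage markers (15 of 25 higher, 18 higher alone, median 1.70, camera adjusted p = 0.0012) were higher as lists at 12 h. They did not hold (adjusted p = 0.705 to 0.729 with an estimated correlation). LGALS3 rose by 2.00 and LYZ by 4.08. Glycolysis (5 of 23 higher and 1 lower, median 1.08, camera adjusted p = 2.16e-04), fast fibre (1 of 13 higher, none alone, median 1.06, camera adjusted p = 0.00704) and cell death genes (11 of 18 higher, 14 higher alone, median 0.86, camera adjusted p = 4.65e-04) were higher. The calls were lost (adjusted p = 0.635 to 0.729 with an estimated correlation). Unfolded protein (10 of 22 higher, 11 higher alone, median 0.77, camera adjusted p = 2.58e-05) and oxidative stress, haem and metal genes (7 of 17 higher and 2 lower, median 0.55, camera adjusted p = 0.0192) were higher. Neither stayed (adjusted p = 0.635 with an estimated correlation). Hypoxia (8 of 20 higher and 2 lower, 9 higher and 2 lower alone, median 0.50, camera adjusted p = 0.0437) and muscle wasting and autophagy genes (8 of 28 higher and 2 lower, 9 higher and 2 lower alone, median 0.30, camera adjusted p = 0.00616) were higher. Both went (adjusted p = 0.635 with an estimated correlation). Contractile (3 of 31 higher and 16 lower, 5 higher and 17 lower alone, median -0.87, camera adjusted p = 0.0208) and slow fibre genes (11 of 12 lower, 12 lower alone, median -1.64, camera adjusted p = 1.28e-04) were lower. Those calls were lost (adjusted p = 0.635 to 0.736 with an estimated correlation). MYOT (-1.70) and ACTN2 (-1.80) fell. Oxidative phosphorylation (15 of 40 lower, 16 lower alone, median -0.58, camera adjusted p = 2.31e-06) and the tricarboxylic acid cycle (8 of 20 lower, 13 lower alone, median -0.57, camera adjusted p = 3.16e-05) were lower. They too were lost (adjusted p = 0.635 to 0.701 with an estimated correlation). Fatty acid use (3 of 26 higher and 20 lower, 3 higher and 21 lower alone, median -1.16, camera adjusted p = 5.14e-07), adipocyte (4 of 10 lower, median -0.83, camera adjusted p = 0.0208) and pericyte markers (10 of 14 lower, median -0.99, camera adjusted p = 1.24e-04) were lower. None kept its call (adjusted p = 0.635 with an estimated correlation).

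EdgeR called 2918 genes at 12 h (1535 higher, 1383 lower; 1043 and 1343 scaled by column totals), 590 and 532 by at least 2-fold, again over libraries that share animals. Without replicate 1 there were 1827. Adding the 5 sets gave 2483 genes, 2030 of them shared. BARX2 (edgeR adjusted p = 0.0598), adipocyte markers (camera adjusted p = 0.0658) and hypoxia (0.0641) were not among these calls. In the 2 libraries of set 4 against its 4 controls 2161 genes were called, without the fast fibre list (camera adjusted p = 0.0864).

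At 16 h, CEMIP, a hyaluronan-degrading protein (chromosome 7, 49622534 to 49792547), rose from 0.105 ± 0.145 to 25.5 ± 19.8 CPM (7.74 ± 0.95). ST14 (chromosome 9, 56888246 to 56929771) rose from 0.194 ± 0.15 to 26.7 ± 10.3 CPM (7.01 ± 0.59) and HAS1 by 5.68 ± 0.87. These 3 had under 3 counts per control library on average. LOXL4 rose (log2 fold change 6.41 ± 0.48 (SE), 275 ± 90.2 CPM (SD, n = 4) against 3.19 ± 2.38 CPM (SD, n = 9), edgeR adjusted p = 7.05e-11). SPP1, which encodes osteopontin (chromosome 8, 131077786 to 131085334), rose as well (log2 fold change 5.82 ± 0.81 (SE), 302 ± 152 CPM (SD, n = 4) against 5.35 ± 3.6 CPM (SD, n = 9), edgeR adjusted p = 1.29e-06). RGS8, a regulator of G-protein signalling, rose by 5.69 ± 0.49. TECRL, a reductase-like gene of muscle (chromosome 8, 62542452 to 62646084), fell from 132 ± 105 to 2.53 ± 1.78 CPM (-5.71 ± 1.07). The calcium channel subunit CACNA2D3 (-6.24 ± 0.88), BARX2 (-5.99 ± 1.10) and the Wnt enhancer RSPO3 (-5.53 ± 0.96) fell too.

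All 40 measured nuclear-encoded oxidative phosphorylation genes fell at 16 h (40 of 40 lower, median -1.44, camera adjusted p = 4.20e-15). As a list they did not hold (adjusted p = 0.635 with an estimated correlation). The tricarboxylic acid cycle (20 of 20 lower, median -1.12, camera adjusted p = 2.68e-07) and slow fibre genes (12 of 12 lower, median -2.61, camera adjusted p = 1.99e-05) were lower. Both calls went (adjusted p = 0.635 with an estimated correlation). Contractile genes (1 of 31 higher and 22 lower, median -1.43, camera adjusted p = 6.21e-05) and fatty acid use (3 of 26 higher and 21 lower, median -1.72, camera adjusted p = 3.59e-06) were lower. Neither held its call (adjusted p = 0.635 with an estimated correlation). Mitochondrially encoded genes (11 of 12 lower, median -1.17, camera adjusted p = 0.00118), ribosomal proteins (1 of 34 higher and 20 lower, median -0.50, camera adjusted p = 4.38e-04) and pericyte markers (9 of 14 lower, 1 higher and 10 lower alone, median -0.997, camera adjusted p = 0.00921) were lower. None stayed (adjusted p = 0.635 to 0.736 with an estimated correlation). Macrophage (19 of 25 higher, 20 higher alone, median 2.10, camera adjusted p = 1.01e-05) and neutrophil markers (10 of 11 higher, median 3.62, camera adjusted p = 0.00312) were higher. These calls fell away (adjusted p = 0.635 to 0.675 with an estimated correlation). Glucocorticoid-responsive (12 of 18 higher, median 1.10, camera adjusted p = 0.00238) and muscle wasting genes (15 of 28 higher and 3 lower, median 0.48, camera adjusted p = 0.0018) were higher. Their calls also fell away (adjusted p = 0.635 with an estimated correlation). TSC22D3 rose by 1.35, TRIM63 by 3.37 and FBXO32 by 2.05. Matrix (12 of 30 higher and 1 lower, median 0.72, camera adjusted p = 0.00295) and oxidative stress genes (9 of 17 higher and 1 lower, 9 higher and 2 lower alone, median 0.61, camera adjusted p = 0.00921) were higher. Each was lost (adjusted p = 0.635 to 0.672 with an estimated correlation). Unfolded protein (11 of 22 higher and 2 lower, 11 higher and 3 lower alone, median 0.83, camera adjusted p = 0.00589), cell death (12 of 18 higher, median 0.98, camera adjusted p = 0.00176) and endothelial activation genes (9 of 13 higher, median 1.06, camera adjusted p = 0.00635) were higher. No call remained (adjusted p = 0.635 to 0.675 with an estimated correlation). HK2, the hexokinase of muscle, rose by 4.06 ± 0.37 from 95.9 ± 47 CPM.

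EdgeR called 4995 genes at 16 h (2380 higher, 2615 lower), 1022 and 1128 by at least 2-fold, with the same limit on shared animals. Scaling by column totals gave 3645 higher and 1355 lower. All 4 libraries were in set 1. With 5 sets as a term 2575 genes were called, 2454 of them shared, and 2750 against the 2 controls of that set. All 17 lists passed with it in the same direction.

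**Figure D4:**
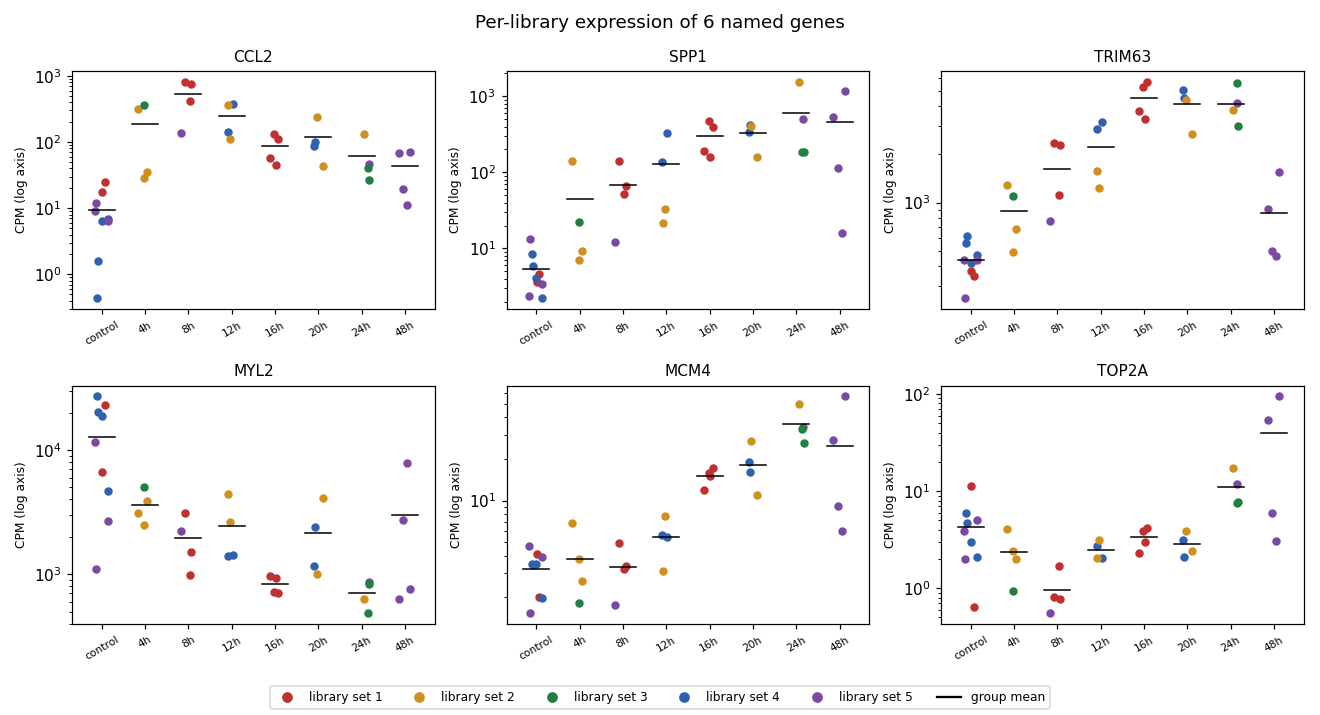
CPM (log axis) of CCL2, SPP1, TRIM63, MYL2, MCM4 and TOP2A in each library by group, coloured by library set, with lines through the group means. CCL2 is already high at 4 h, TRIM63 is highest at 16 to 24 h, and TOP2A is lower at 8 h than in the controls and highest at 48 h.

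At 20 h, the trehalase gene TREH rose (6.30 ± 0.74, control 0.0636 ± 0.0485 CPM). MARCO, a scavenger receptor of macrophages (chromosome 15, 24502935 to 24541286), rose from 0.16 ± 0.26 to 10.7 ± 10.1 CPM (6.02 ± 0.85). SLC11A1, a metal transporter of phagosomes (chromosome 15, 120434100 to 120446396), rose (log2 fold change 5.80 ± 0.72 (SE), 29.7 ± 15.8 CPM (SD, n = 4) against 0.509 ± 0.367 CPM (SD, n = 9), edgeR adjusted p = 2.40e-07), and AQP9, a channel for water and glycerol, by 5.83 ± 0.78. SPP1 (5.96 ± 0.82) and LOXL4 (5.71 ± 0.47) rose too. SBK2, a kinase gene that varied widely between control libraries, fell from 107 ± 85.1 to 0.216 ± 0.11 CPM (-8.94 ± 1.81). PLIN5, a coat protein of lipid droplets (chromosome 2, 74304613 to 74314314), fell from 107 ± 72.7 to 4.05 ± 3.52 CPM (-4.76 ± 0.84). THRSP, a regulator of fat synthesis (-4.73 ± 0.80), and BARX2 (-5.97 ± 1.12) were also lower.

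Oxidative phosphorylation (39 of 40 lower, 40 lower alone, median -1.53, camera adjusted p = 1.11e-16) and the tricarboxylic acid cycle (20 of 20 lower, median -1.24, camera adjusted p = 4.24e-09) were lower at 20 h as lists. Both lost their calls (adjusted p = 0.635 with an estimated correlation). Fatty acid use (22 of 26 lower, median -1.80, camera adjusted p = 5.68e-09) and mitochondrially encoded genes (9 of 12 lower, 10 lower alone, median -1.14, camera adjusted p = 0.00122) were lower. These calls were lost also (adjusted p = 0.635 with an estimated correlation). Slow fibre (12 of 12 lower, median -1.78, camera adjusted p = 0.0018) and contractile genes (1 of 31 higher and 19 lower, median -1.11, camera adjusted p = 0.00262) were lower. Neither remained (adjusted p = 0.667 to 0.675 with an estimated correlation). Pericyte (9 of 14 lower, median -1.11, camera adjusted p = 2.86e-04) and adipocyte markers (6 of 10 lower, 8 lower alone, median -1.51, camera adjusted p = 0.0081) were lower. These went too (adjusted p = 0.635 with an estimated correlation). CNN1 (-1.98) and ADIPOQ (-2.97) fell. Macrophage (21 of 25 higher, median 2.19, camera adjusted p = 7.49e-06) and neutrophil markers (10 of 11 higher, median 3.28, camera adjusted p = 0.00704) were higher. They were lost (adjusted p = 0.635 to 0.701 with an estimated correlation). Unfolded protein (13 of 22 higher and 3 lower, median 0.89, camera adjusted p = 0.0018), muscle wasting (11 of 28 higher and 3 lower, median 0.34, camera adjusted p = 0.00534) and cell death genes (11 of 18 higher, median 0.98, camera adjusted p = 0.00389) were higher. Not one held (adjusted p = 0.635 to 0.652 with an estimated correlation).

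EdgeR called 4851 genes at 20 h (2389 higher, 2462 lower), 925 and 1174 by at least 2-fold, from libraries that share animals. Scaled by column totals 3620 were higher and 1456 lower. Given 5 sets as a term it called 4642, 4092 of them shared, with all 13 lists in the same direction. In the 2 libraries of set 4 against its 4 controls it called 3521.

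At 24 h, SPP1 rose (log2 fold change 6.84 ± 0.84 (SE), 610.1 ± 651 CPM (SD, n = 4) against 5.35 ± 3.6 CPM (SD, n = 9), edgeR adjusted p = 1.54e-07). LY6G6C, a member of the LY6 family, rose by 6.06 ± 0.64, TARS3 by 5.49 ± 0.58 and SLC11A1 by 5.48 ± 0.72. The macrophage receptor TREM2 (chromosome 7, 36465921 to 36471509) rose by 5.42 ± 0.72. ARG1, which encodes arginase, rose by 5.44 ± 1.14 to 16.1 ± 19.8 CPM. TECRL (-7.19 ± 1.17) and EXTL1, a glycosyltransferase of heparan sulfate (-6.01 ± 0.89), fell. LGI1 (-5.51 ± 0.96) and CATSPER4, a subunit of a sperm calcium channel (-5.38 ± 0.86), fell too.

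Contractile (23 of 31 lower, median -1.53, camera adjusted p = 1.53e-06), slow fibre (12 of 12 lower, median -2.55, camera adjusted p = 5.54e-05) and calcium handling genes (2 of 19 higher and 12 lower, 2 higher and 13 lower alone, median -1.05, camera adjusted p = 0.00512) were lower at 24 h. Their list calls were lost (adjusted p = 0.635 with an estimated correlation). MYBPC1 (-4.08) and ATP2A2, the slow fibre's calcium pump (-3.88), fell. Oxidative phosphorylation (40 of 40 lower, median -1.54, camera adjusted p = 4.40e-16) and the tricarboxylic acid cycle (20 of 20 lower, median -1.32, camera adjusted p = 4.18e-09) were lower. Both were lost again (adjusted p = 0.635 with an estimated correlation). Fatty acid use (1 of 26 higher and 21 lower, median -1.86, camera adjusted p = 5.14e-07) and pericyte markers (9 of 14 lower, median -0.68, camera adjusted p = 0.0052) were lower. Neither one held (adjusted p = 0.635 with an estimated correlation). Macrophage markers (21 of 25 higher, median 2.49, camera adjusted p = 1.51e-05) and cell cycle genes (11 of 22 higher, median 1.38, camera adjusted p = 0.0019) were higher. Those were lost (adjusted p = 0.635 to 0.729 with an estimated correlation). GPNMB rose by 3.15, and the replication helicase genes MCM2 and MCM4 by 3.50 and 3.47. Oxidative stress (10 of 17 higher and 1 lower, median 1.14, camera adjusted p = 0.00616), muscle wasting (15 of 28 higher and 6 lower, 16 higher and 6 lower alone, median 0.57, camera adjusted p = 0.00917) and cell death genes (13 of 18 higher and 1 lower, median 0.96, camera adjusted p = 0.0416) were higher. All lost their calls (adjusted p = 0.635 to 0.734 with an estimated correlation). FTL, the ferritin light chain, was 10.8 ± 10.7 CPM against 0.384 ± 0.27, with 21.3 and 18.8 CPM in the 2 libraries of set 3. VEGFA, which drives vessel growth, was lower (-2.90 ± 0.43), and the glucocorticoid-responsive TSC22D3 higher (2.28 ± 0.16).

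EdgeR called 5071 genes at 24 h (2521 higher, 2550 lower), 1037 and 1223 by at least 2-fold, the libraries sharing animals. Scaled by column totals 4538 were higher and 1178 lower. In the fit with 5 sets 4431 were called, 4077 of them shared, the pericyte list not among the calls (camera adjusted p = 0.0638). Only 1 library was in set 5, and against its 3 controls 1100 were called with the spread taken from other groups, which does not test single genes.

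At 48 h, SPP1 rose (log2 fold change 6.43 ± 0.83 (SE), 459 ± 528 CPM (SD, n = 4) against 5.35 ± 3.6 CPM (SD, n = 9), edgeR adjusted p = 4.22e-06). MARCO (6.81 ± 0.85), TREH (7.32 ± 0.72) and TREM2 (5.38 ± 0.72), under 3 counts per control library on average, rose. SLC11A1 (5.13 ± 0.72) and LY6G6C (5.06 ± 0.64) rose too. CNN1, the smooth muscle calponin (chromosome 2, 70183370 to 70190756), fell (log2 fold change -1.66 ± 0.25 (SE), 18 ± 5.97 CPM (SD, n = 4) against 56.5 ± 20.4 CPM (SD, n = 9), edgeR adjusted p = 3.77e-05). ALDH1A2, an enzyme of retinoic acid synthesis (-2.91 ± 0.66), the zinc finger gene PHF24 (-1.86 ± 0.44) and HHIP (-1.83 ± 0.43) were also lower.

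Cell cycle genes (20 of 22 higher, median 2.40, camera adjusted p = 9.96e-10) and macrophage markers (24 of 25 higher, 25 higher alone, median 1.94, camera adjusted p = 4.68e-12) were higher at 48 h. As lists they were lost (adjusted p = 0.635 with an estimated correlation). TOP2A rose by 3.19 and MCM4 by 2.96. Neutrophil markers (5 of 11 higher, median 1.75, camera adjusted p = 0.0199) and class II antigen presentation (5 of 7 higher, median 0.82, camera adjusted p = 0.00155) were higher. Neither call stood (adjusted p = 0.635 to 0.729 with an estimated correlation). Endothelial activation (8 of 13 higher, median 1.06, camera adjusted p = 0.0016), cytokines (7 of 18 higher, 9 higher and 1 lower alone, median 0.79, camera adjusted p = 0.0216) and matrix genes (10 of 30 higher, 11 higher alone, median 0.54, camera adjusted p = 1.67e-04) were higher. None stood (adjusted p = 0.635 with an estimated correlation). Complement and clotting (9 of 21 higher, 10 higher and 1 lower alone, median 0.89, camera adjusted p = 0.0409) and interferon response (6 of 24 higher, median 0.38, camera adjusted p = 0.00377) were higher. Both fell away (adjusted p = 0.638 to 0.717 with an estimated correlation). Oxidative stress (5 of 17 higher, median 0.48, camera adjusted p = 0.022) and cell death genes (11 of 18 higher, 13 higher and 1 lower alone, median 0.84, camera adjusted p = 0.00225) were higher. They went as well (adjusted p = 0.635 with an estimated correlation). Slow fibre (10 of 12 lower, 11 lower alone, median -1.83, camera adjusted p = 2.34e-05), contractile (16 of 31 lower, 20 lower alone, median -1.18, camera adjusted p = 3.45e-07) and oxidative phosphorylation genes (22 of 40 lower, 32 lower alone, median -0.92, camera adjusted p = 2.41e-16) were lower. No call held (adjusted p = 0.635 with an estimated correlation). Tricarboxylic acid (8 of 20 lower, 14 lower alone, median -0.67, camera adjusted p = 1.02e-07) and fatty acid genes (12 of 26 lower, 21 lower alone, median -0.97, camera adjusted p = 4.24e-09) were lower. Their calls were not kept (adjusted p = 0.635 with an estimated correlation). Adipocyte markers (4 of 10 lower, 5 lower alone, median -0.84, camera adjusted p = 0.00635) and heat shock genes (1 of 19 higher and 5 lower, 2 higher and 13 lower alone, median -0.55, camera adjusted p = 0.00136) were lower. Nor did these hold (adjusted p = 0.635 with an estimated correlation).

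EdgeR called 1906 genes at 48 h (1205 higher, 701 lower), 637 and 204 by at least 2-fold, the libraries sharing animals. Scaled by column totals 3050 were higher and 298 lower. There were 368 calls without replicate 1 and 2732 without replicate 4. Without replicates 2 and 4, which lay nearest to control libraries, there were 3448 (1848 higher, 1600 lower). With 5 sets as a term 1108 genes were called, 1019 of them shared, PHF24 not among them (edgeR adjusted p = 0.0732), and with 4 sets 2283. Against the 3 controls of set 5, the set of all 4 libraries, 317 were called, without ALDH1A2 (edgeR adjusted p = 0.0766) and PHF24 (0.285). The cytokine (camera adjusted p = 0.0737), slow fibre (0.0822), heat shock (0.0651) and complement lists (0.215) did not pass there.

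Genes that differed among the 7 times were tested together within the fit to all 37 libraries. TSC22D3, a gene induced by glucocorticoids (chromosome X, 88171325 to 88233583), had means of 197, 126, 215, 521, 412, 995 and 316 CPM from 4 to 48 h and 205 in the controls (edgeR adjusted p = 1.63e-11). PKDCC, a secreted kinase (159 CPM), the ubiquitin ligase-like LONRF3 (188 CPM), the transcription factor CEBPG (131 CPM) and the collagen mRNA-binding LARP6 (67.9 CPM) had their highest means at 8 h. The controls had 30.5, 20.2, 35.8 and 17.4 CPM. VPS26C, of endosomal sorting (26.3 CPM), the lysosomal TMEM192 (18.1 CPM), the annexin ANXA4 (72.8 CPM) and the pyrimidine synthesis gene DHODH (19.4 CPM) had theirs at 24 h. The control means were 8.71, 7.14, 46.5 and 7.38 CPM. CNN1 was highest at 4 h (88 CPM) and lowest at 20 h (14.3 CPM). These 10 genes had the smallest p-values, and all passed with the 5 sets as a term.

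EdgeR called 6617 genes among the 7 times and 7830 among all 8 groups, on libraries that share animals. Of the 6617, 1331 had their highest mean at 4 h, 1424 at 8 h, 314 at 12 h, 624 at 16 h, 445 at 20 h, 1164 at 24 h and 1315 at 48 h. Without 12 h replicate 3 or replicate 1 the count at 12 h was 176 or 591. With 5 sets as a term 4328 genes were called, 4242 of them shared. Of the 4328, 496, 923, 267, 219, 457, 1058 and 908 were highest at the successive times.

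Over log2 hours after injury, MARCO rose by 2.04 ± 0.30 per doubling of time. TOP2A, a topoisomerase of dividing cells (chromosome 12, 22001300 to 22028452), rose by 1.27 ± 0.19, SPP1 by 1.22 ± 0.30, LY6G6C by 1.20 ± 0.28 and SBK2 by 1.52 ± 0.37. ARC (-1.55 ± 0.33), XIRP1, an actin-binding repeat protein of muscle (-1.31 ± 0.27), and the sphingomyelin synthase gene SGMS2 (-1.30 ± 0.21) fell over time. The membrane channel gene PANX1 (-1.22 ± 0.22) and PTX3, a pentraxin of innate immunity (-1.17 ± 0.34), fell as well. EdgeR called 2257 genes (1271 rising, 986 falling) over the 28 libraries, which share animals. It called 2818 with 5 sets as a term, 1799 of them shared in the same direction. SBK2 rested on 48 h replicate 4, at 227 CPM against 0.938 to 8.95 CPM in the other 48 h libraries. Its slope turned to -1.35 without the 48 h libraries (edgeR adjusted p = 0.0388) and to -0.14 with the 5 sets (0.863).

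Successive times were compared to find when genes changed. From 4 to 8 h, CXCL8, the neutrophil-attracting chemokine (chromosome 8, 69932646 to 69935861), rose from 3.59 ± 1.93 to 139.8 ± 154 CPM (5.26 ± 1.38). With 5 sets this was 0.63 (edgeR adjusted p = 0.959) and with 4 sets -0.36. LTB4R, the leukotriene B4 receptor, rose from 0.305 ± 0.283 to 9.74 ± 7.93 CPM (5.05, 1.65 with 5 sets). PHGDH, of serine synthesis, fell (log2 fold change -3.62 ± 0.50 (SE), 0.775 ± 0.477 CPM (SD, n = 4) against 9.68 ± 4.71 CPM (SD, n = 4), edgeR adjusted p = 5.01e-05). The retinoic acid-binding CRABP1 (-3.61 ± 0.68) and NRN1 (-4.78 ± 1.21) fell too. C1QBP, a gene that defined the library sets, differed by 5.76 ± 1.40, and by -2.20 with 5 sets. Of 9 lists called, neutrophil markers (11 of 11 higher, median 3.37, camera adjusted p = 0.00166) were higher and pericyte (7 of 14 lower, median -0.72, camera adjusted p = 0.00335) and fibroblast markers (6 of 17 lower, 7 lower alone, median -0.82, camera adjusted p = 0.00398) lower as lists both without and with the sets. None held (adjusted p = 0.858 with an estimated correlation). Ribosomal proteins were lower without the sets (10 of 34 lower, median -0.35, camera adjusted p = 6.99e-04; adjusted p = 0.858 with an estimated correlation) and had a median of 0.20 with them (camera adjusted p = 0.0198). EdgeR called 2950 genes (1502 higher, 1448 lower) in libraries that share animals. No set held both times. With 5 sets edgeR called 0 genes (841 at an unadjusted p under 0.05, DESeq2 without sets 3259).

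From 8 to 12 h, NRN1 (3.68 ± 1.19), the anion transporter gene SLC26A7 (3.44 ± 0.99) and CRABP1 (3.37 ± 0.68) rose. The centromere gene CENPU (-3.50 ± 0.91), C1QBP (-6.79 ± 1.58) and TMEM238 (-3.87 ± 1.03) fell. With 5 sets they were -2.15, -1.98 and -0.24, the last 2 following sets. Of 9 lists called, interferon response (2 of 24 lower, 6 lower alone, median -0.60, camera adjusted p = 7.78e-04) was lower and pericyte markers (2 of 14 higher, median 0.37, camera adjusted p = 0.0456) higher as lists without and with the sets. Neither was kept (adjusted p = 0.858 with an estimated correlation). Immediate early genes were lower only without them (3 of 24 lower, median -0.99, camera adjusted p = 6.86e-05; adjusted p = 0.858 with an estimated correlation). EdgeR called 1138 genes (672 of them higher; scaled by column totals 511 higher and 137 lower) in libraries that share animals, and 135 without 12 h replicate 3. Again no set held libraries of both times. With 5 sets edgeR called 0 genes (873 at an unadjusted p under 0.05; DESeq2 without the term called 1540).

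From 12 to 16 h, CEACAM16, of the carcinoembryonic antigen family, fell (log2 fold change -4.22 ± 0.53 (SE), 0.599 ± 0.281 CPM (SD, n = 4) against 11.4 ± 4.97 CPM (SD, n = 4), edgeR adjusted p = 1.58e-05). LYZ, the lysozyme gene of phagocytes (-3.42 ± 0.69), and NRN1 (-4.47 ± 1.23) fell as well. C1QBP (6.31 ± 1.57), TMEM238 (4.02 ± 1.03) and the mitochondrial ribosome gene MRPL57 (3.78 ± 1.17), which follow the sets, were higher. With 5 sets they were at 1.21, 0.16 and -0.55, and MRPL57 at -0.99 with 4 sets. Of 16 lists called, 7 kept their call and direction with the sets. Among them oxidative phosphorylation (22 of 40 lower, 33 lower alone, median -0.90, camera adjusted p = 5.86e-12), contractile genes (2 of 31 lower, none alone, median -0.97, camera adjusted p = 5.15e-04) and glycolysis (3 of 23 lower, median -0.78, camera adjusted p = 0.0176) were lower as lists. These did not stay (adjusted p = 0.858 with an estimated correlation). Fatty acid use (2 of 26 lower, median -0.32, camera adjusted p = 0.0467) was lower, with a median of 0.0622 when scaled by column totals, and muscle wasting higher (2 of 28 higher, median 0.18, camera adjusted p = 0.0394). Neither stood (adjusted p = 0.858 to 0.879 with an estimated correlation). EdgeR called 1339 genes (444 higher, 895 lower; 1342 and 265 scaled by column totals) in libraries that share animals, and 567 without 16 h replicate 1. All 4 libraries at 16 h and none at 12 h were in set 1. With 5 sets edgeR called 0 genes (548 at an unadjusted p under 0.05; DESeq2 without the term called 1673).

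From 16 to 20 h, LYZ rose (3.74 ± 0.70), as did the sodium channel regulator NALF2 (log2 fold change 2.33 ± 0.50 (SE), 19.7 ± 2.62 CPM (SD, n = 4) against 3.9 ± 0.881 CPM (SD, n = 4), edgeR adjusted p = 0.0114). TUBB, a beta tubulin (2.18 ± 0.47; 0.44 with 5 sets), rose too. C1QBP (-5.59 ± 1.41), MRPL57 (-5.43 ± 1.30) and TMEM238 (-4.04 ± 0.99) were lower, but -0.24, -1.20 and -0.034 with 5 sets. Of 12 lists called, adipocyte (3 of 10 lower, 7 lower alone, median -1.44, camera adjusted p = 3.22e-05) and fibroblast markers (none of 17 singly, 1 lower alone, median -0.60, camera adjusted p = 0.0184) were lower as lists without and with the sets. They were not kept (adjusted p = 0.858 with an estimated correlation). Erythrocyte and platelet markers (1 of 3 lower, 2 lower alone, median -1.46, camera adjusted p = 0.0456) and matrix genes (1 of 30 lower, median -0.71, camera adjusted p = 4.65e-06) were also lower either way. Nor were these (adjusted p = 0.858 with an estimated correlation). Ribosomal proteins were higher only without the sets (1 of 34 higher, 18 higher alone, median 0.47, camera adjusted p = 2.01e-10; adjusted p = 0.858 with an estimated correlation). EdgeR called 203 genes (95 higher, 108 lower) in libraries that share animals, and 65 to 131 with any 1 of the 8 libraries left out. No set held both times. With 5 sets edgeR called 0 genes (645 at an unadjusted p under 0.05; DESeq2 without the term called 412).

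From 20 to 24 h, PCK1, the rate-limiting enzyme of glucose synthesis (chromosome 17, 57930507 to 57936523), rose (log2 fold change 4.68 ± 0.80 (SE), 11.8 ± 6.63 CPM (SD, n = 4) against 0.477 ± 0.438 CPM (SD, n = 4), edgeR adjusted p = 0.00121). The smooth muscle actin ACTG2 (3.23 ± 0.70) and ND6, a gene that defined sets (4.49 ± 0.80), rose too. CISH, a cytokine signalling inhibitor (-2.73 ± 0.74), and the linker histone H1-4 (-2.64 ± 0.55) fell. Of 13 lists called, 9 kept their call and direction with the sets. Among them cell cycle (1 of 22 higher, median 1.24, camera adjusted p = 3.22e-05) and adipocyte lists (3 of 10 higher, median 1.01, camera adjusted p = 0.0032) were higher. Both dropped out (adjusted p = 0.858 with an estimated correlation). Contractile (1 of 31 lower, median -0.66, camera adjusted p = 6.88e-05), hypoxia (1 of 20 lower, 3 lower alone, median -0.37, camera adjusted p = 4.01e-04) and glycolysis genes (1 of 23 lower, median -0.51, camera adjusted p = 0.00629) were lower. All dropped out (adjusted p = 0.858 with an estimated correlation). EdgeR called 302 genes (182 higher, 120 lower; 173 and 51 scaled by column totals) in libraries that share animals, and 98 without 24 h replicate 4. With 5 sets 54 were called, 48 of them shared. CISH (edgeR adjusted p = 0.211) and H1-4 (0.148) were not among them.

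From 24 to 48 h, AQP4, the water channel of the muscle fibre membrane (chromosome 6, 111407632 to 111422169), rose (log2 fold change 4.85 ± 0.63 (SE), 133 ± 126 CPM (SD, n = 4) against 4.65 ± 2.89 CPM (SD, n = 4), edgeR adjusted p = 7.67e-06). The kelch protein KBTBD13 (5.25 ± 0.99) and SBK2 (7.53 ± 1.68, mostly in replicate 4) rose too. ZFAND2A, a stress-induced zinc finger protein, fell (log2 fold change -3.36 ± 0.66 (SE), 9.96 ± 6.58 CPM (SD, n = 4) against 103 ± 16.1 CPM (SD, n = 4), edgeR adjusted p = 6.41e-04). PCK1 (-4.06 ± 0.76) and the carnitine transporter SLC16A9 (-2.99 ± 0.46) fell as well. Of 11 lists called, calcium handling (9 of 19 higher, 10 higher alone, median 0.82, camera adjusted p = 9.17e-04) and interferon response (5 of 24 higher and 1 lower, 9 higher and 1 lower alone, median 0.67, camera adjusted p = 0.00599) were higher as lists with and without the sets, and muscle wasting lower (2 of 28 higher and 9 lower, 4 higher and 11 lower alone, median -0.45, camera adjusted p = 6.63e-04). None of them held (adjusted p = 0.858 with an estimated correlation). Oxidative phosphorylation (21 of 40 higher, 31 higher alone, median 0.66, camera adjusted p = 2.54e-06) and tricarboxylic acid genes (13 of 20 higher, 15 higher alone, median 0.66, camera adjusted p = 6.88e-05) were higher. Neither was held (adjusted p = 0.858 with an estimated correlation). Contractile (10 of 31 higher, 12 higher alone, median 0.46, camera adjusted p = 0.0124), slow fibre (6 of 12 higher, median 1.08, camera adjusted p = 0.0341) and fatty acid genes (14 of 26 higher and 2 lower, 15 higher and 2 lower alone, median 0.72, camera adjusted p = 0.0133) were higher. These were not held (adjusted p = 0.858 with an estimated correlation). Without 48 h replicates 2 and 4 the medians of these 5 were -0.19, -0.12, -0.21, -0.24 and 0.0099, and none passed (camera adjusted p = 0.0798 to 0.878). EdgeR called 1832 genes (964 higher, 868 lower; 575 and 689 scaled by column totals) in libraries that share animals. It called 1048 without 48 h replicate 4 and 551 without replicates 2 and 4. With 5 sets 842 were called, 764 of them shared, SBK2 not among them (edgeR adjusted p = 0.0648).

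Genes changed in the same direction at all 7 times against control numbered 253 (131 higher, 122 lower). TIMP1, PLAU and RUNX1 were among those higher, with 5 sets as well. PRRX1, MYL2 and GPAM were lower, but with 5 sets not called at 48 h (edgeR adjusted p = 0.225, 0.199 and 0.275), nor was MYL2 at 4 h (0.164). Independent lists of the same sizes would share 0.0804 higher and 0.0519 lower, but the 7 comparisons share their 9 controls. In 20 simulated sets of unchanged groups edgeR gave 0 such genes, which does not test library sets or shared animals. With 4, 12, 20 and 48 h against 5 odd-numbered controls and 8, 16 and 24 h against 4 even-numbered ones, 12 genes were higher and 3 lower at all 7 times. With 5 sets as a term there were 42 and 8. The count was 61 without 48 h replicate 1 and 428 without 48 h replicate 4.

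Some lists passed at no time and in no successive comparison. Satellite cell and myogenic genes moved apart at 8 h, RUNX1 rising by 5.49 ± 0.50 and GADD45A by 4.16 ± 0.46 while IGF1 (-2.52 ± 0.34) and IGFBP5 (-2.47 ± 0.46) fell. Of 24 members 8 were higher and 8 lower (8 and 8 alone, median -0.13, camera adjusted p = 0.873). Circadian clock genes did so too at 16 h. Of 18 members 3 were higher and 3 lower (3 and 3 alone, camera adjusted p = 0.94). Schwann cell and nerve (at 8 h 3 of 7 higher and 1 lower, camera adjusted p = 0.499) and keratinocyte lists (at 24 h 2 of 5 higher and 2 lower, DSP 0.62 and TP63 -2.05, 0.837) were measured by few members. So were mast cells (at 24 h 0 of 3 higher and 1 lower, GATA2 -1.35, camera adjusted p = 0.499) and lymphocytes (2 members, NKG7 2.77 and JCHAIN -1.53 at 24 h, 0.962). Endothelial cell markers (at 16 h 2 of 14 higher and 4 lower, camera adjusted p = 0.646) and erythrocyte and platelet markers (2 of 3 higher and 1 lower, 0.52) passed at no time against control. EMCN (-1.49), TEK (-1.21) and CD34 (-1.11) fell at 16 h, and PLVAP rose at 24 h (1.04).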

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

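Of the tests here, that of library sets at 48 h and every fit with them were chosen only after the result was seen. Tests of other splits were stated before. Those of uninjured tissue and 12 h libraries were too, but use sets defined after the data were seen.

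Single libraries stood apart from the rest of their group in 23 of 168 groups and measures compared, where chance marks about 1 in 20 groups. The column total was 21.5 M in 4 h replicate 3 (others 10.9 to 11.4) and 11.08 M in 12 h replicate 4 (others 10.1). The 10 most abundant genes took 26.4% of counts in 8 h replicate 3 (others 27.2%) and 29.1% in 20 h replicate 1 (others 17.1 to 18.5%). TMM factors stood apart in 4 h replicate 2 (0.887), 8 h replicate 3 (0.932), 20 h replicate 1 (0.874, others 1.22 to 1.26) and 24 h replicate 3 (1.41).

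Control replicate 2 was the highest control for FOSL1 (2.37 CPM, others 0.492 to 1.41), AMCF-II (0.639 CPM) and LOXL4 (9.31 CPM, others 1.63 to 3.69), and control replicate 7 for MARCO (0.769 CPM) and LY6G6C (1.54 CPM). At later times FOSL1 stood apart in 24 h replicate 3 (13.7 CPM), AMCF-II in 20 h replicate 4 (9.09 CPM) and 48 h replicate 1 (2.51 CPM), ST14 in 24 h replicate 1 (9.12 CPM), SPP1 in 4 h replicate 2 (139 CPM, others 7.09 to 22.4), MARCO in 8 h replicate 4 (0.11 CPM) and TECRL in 8 h replicate 4 (15.0 CPM, others 2.52 to 3.89). SBK2 was 0.733 CPM in 24 h replicate 2 and 227 CPM in 48 h replicate 4, where TECRL was 76.6 CPM (others 2.39 to 12.1).

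Gene lists that differed between successive times, by camera on the difference with and without the library sets, numbered 34 (median log2 differences follow). With an estimated correlation none was called (lowest adjusted p = 0.858), and fry called 0 to 2 lists in each pair. From 4 to 8 h these were neutrophil (3.37), pericyte (-0.72) and fibroblast markers (-0.82), and from 8 to 12 h pericyte markers (0.37) and interferon response (-0.60). From 12 to 16 h they were contractile (-0.97), fast fibre (-0.92), oxidative phosphorylation (-0.90), tricarboxylic acid (-0.51), glycolysis (-0.78), fatty acid (-0.32) and wasting genes (0.18). From 16 to 20 h they were erythrocyte and platelet (-1.46), fibroblast (-0.60) and adipocyte markers (-1.44) and matrix genes (-0.71). From 20 to 24 h they were immediate early (-0.49), contractile (-0.66), fast fibre (-0.51), calcium (-0.53), glycolysis (-0.51), unfolded protein (-0.32), hypoxia (-0.37), adipocyte (1.01) and cell cycle genes (1.24). From 24 to 48 h they were immediate early (0.71), contractile (0.46), slow fibre (1.08), calcium (0.82), oxidative phosphorylation (0.66), tricarboxylic acid (0.66), fatty acid (0.72), wasting (-0.45) and interferon genes (0.67). Without 48 h replicates 2 and 4 the contractile (-0.21), slow fibre (-0.24), oxidative phosphorylation (-0.19) and tricarboxylic acid (-0.12) medians turned, fatty acid was 0.00988, and none of the 5 passed (camera adjusted p = 0.0798 to 0.878).

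The 48 h libraries fell apart: replicates 1 and 3 exceeded every control on 77.5% and 59.5% of 819 genes (at least 5 CPM and higher at 16 and at 24 h with and without the library sets), and replicates 2 and 4 on 24.7% and 10.6%. All 4 are in set 5, so the 34.8-point gap tests neither the set nor technical splits in it. Controls left out in turn reached 4.76 to 22.8% (at most 11.11% in set 5), so replicate 4 lies within the range of uninjured tissue, as for tissue outside the injury or a wrong label. For replicate 2, above that range by less than the margin stated beforehand, uninjured tissue cannot be told apart from a weak response. The margin over set 5 controls alone was not tested. Recovery in some animals by 48 h, which the design would allow, was not tested and stays open for both.

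The 12 h libraries also parted: replicates 3 and 4, of set 2, correlated most with 4 h replicates 1 and 2 (0.973 and 0.983) rather than with 12 h replicates 1 and 2. Once the set difference seen at 20 h was removed, their mean correlation with the 4 h libraries of their set exceeded that with 12 h replicates 1 and 2 by 0.00791, down from 0.0345, between the values stated beforehand for and against the set. Over the clock genes their distance to the 4 h mean was 0.815 of that to 12 h replicates 1 and 2, which does not decide on a wrong time label either. The library set and a wrong label cannot be told apart here, because 3 of the 4 h libraries are in set 2, and a difference between animals was not tested.

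Chance was examined by regrouping the libraries of each comparison fitted alone, with 100 splits against control. At 4 h only the real split gave as many genes (1195, highest other 416). So it was at 8 h (4990, 3272), 12 h (2556, 538) and 16 h (5116, 1565). The same held at 20 h (4597, 1976), 24 h (4897, 302) and 48 h (932, 316). As libraries share animals, this cannot exclude chance. The highest other split at 8 h put control replicate 2 with 8 h replicates 1 to 3, all of set 1. Among 35 splits of successive times the real one was highest from 4 to 8 h (1975, 3), 12 to 16 h (1410, 5), 16 to 20 h (444, 0), 20 to 24 h (252, 63) and 24 to 48 h (903, 56). Up to 20 h sets cannot be told from time, as none spans a pair. From 8 to 12 h 2 of 35 splits were as large (real 234), so chance stays open. The other, 8 h replicates 1 to 3 with 12 h replicate 1, called 1218 genes by parting the set 1 libraries. With 5 sets edgeR called 0 genes there (873 at an unadjusted p under 0.05, DESeq2 without sets 1540). For the 7 times (6524, highest other 325) and the slope (2257, 4) the real grouping was the highest of 100.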

How the results depend on the processing

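The library sets, controls of the same set, scaling by column totals, and the fits without 48 h replicates 2 and 4 or without set 2 were chosen only after the results were seen; the other alternatives were listed before. Other size factors, other filters and limma-voom kept every count of genes within 1.5 times, and DESeq2 did so except from 16 to 20 h (412 genes) and from 20 to 24 h (559). Where a setting below moved a count the cause was not tested, unless fewer libraries or a stricter criterion explain it by construction. The few libraries, the counting depth and the shared animals limit all of these values.

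With the fold change tested against 2, edgeR called 46, 917, 163, 762, 762, 868 and 195 genes from 4 to 48 h against control, a stricter criterion. With the 5 sets as a term it called 259 at 4 h, 2575 at 16 h and 1108 at 48 h, 0 in the first 4 successive pairs (841, 873, 548 and 645 at an unadjusted p under 0.05; DESeq2 without sets 3259, 1540, 1673 and 412), 54 from 20 to 24 h, 842 from 24 to 48 h and 4328 among the times, with 22 lists at 4 h, 10 lists from 12 to 16 h, 50 genes changed at all times and 496, 923 and 219 genes highest at 4, 8 and 16 h. With 4 sets it called 259 at 4 h, 2620 at 16 h, 0 from 4 to 8 h and from 16 to 20 h, 7 from 8 to 12 h, 2 from 12 to 16 h and 97 from 20 to 24 h, with 21 lists at 4 h, 5 from 8 to 12 h and 10 from 12 to 16 h. Against controls of the same set there were 2750 genes at 16 h, 1100 at 24 h and 317 at 48 h, with fewer libraries. Without the 8 libraries of set 2 there were 658 at 4 h and, for successive pairs, 128, 243, 64, 20 and 109 up to 24 h. Only 4 h replicate 3 was then left at 4 h, with the spread taken from other groups, so the 658 and 128 do not test 4 h. Fitted alone, 48 h gave 932, 8 to 12 h 234, 16 to 20 h 444 and 24 to 48 h 903. Scaled by totals, 48 h gave 3348, 8 to 12 h 648 and 16 to 20 h 118. Without 48 h replicates 2 and 4 there were 3448 genes at 48 h, 551 from 24 to 48 h and 3634 with a slope, and without all 48 h libraries 3538 with a slope. With separate controls for odd- and even-placed times 15 genes changed at all times.

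With an estimated correlation, camera called 0 of the 38 lists in each of the 13 comparisons (against control 13, 17, 16, 17, 13, 12 and 18 with the preset value, and fry 11, 23, 15, 22, 19, 20 and 19). That setting called 3 raised lists in 20, 20 and 11 of 20 simulated 48 h draws, which lack library sets and shared animals and cannot test it here. In successive pairs fry called 1, 0, 1, 1, 1 and 2 lists and preset camera 9, 9, 16, 12, 13 and 11.

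Some directions turned. With 5 sets the list medians were 0.0865 for immediate early and 0.20 for ribosomal genes from 4 to 8 h, -0.0234 for ribosomal genes from 8 to 12 h, -0.40 for immediate early genes from 12 to 16 h, and 0.69 for immediate early and -0.0579 for complement genes (whose test turned) from 16 to 20 h. With 4 sets they were 0.16 (ribosomal, 4 to 8 h), 0.68 (neutrophil) and 0.0200 (ribosomal, by test; both 8 to 12 h), -0.36 and 0.36 (immediate early, 12 to 16 and 16 to 20 h). Log2 changes with 5 sets were -2.20 for C1QBP (4 to 8 h), -0.55 for MRPL57 (12 to 16 h), -0.14 for the SBK2 slope, 0.76 for CEBPB and -1.06 for ND4L at 24 h, and -0.24 for ND4L and -8.67e-04 for FTL at 4 h. With 4 sets they were -1.80 and 0.22 for C1QBP (4 to 8 and 16 to 20 h), -0.36 for CXCL8 (4 to 8 h), -0.99 for MRPL57, 0.69 for CEBPB and -1.04 for ND4L at 24 h, and -0.28 for ND4L and -0.0399 for FTL at 4 h. Against controls of the same set CEBPB was 1.28, MBP -0.28 and ND4L -0.84 at 24 h, and scaled by totals NQO1 was 0.45 and RPL27 0.48 at 24 h. Without 48 h replicates 2 and 4 the medians from 24 to 48 h were -0.21 (contractile), -0.24 (slow fibre), -0.19 (oxidative phosphorylation), -0.12 (tricarboxylic acid) and 0.00988 (fatty acid, by test). The SBK2 slope was -1.35 without the 48 h libraries, and ND4L at 4 h ran from -0.0309 without 4 h replicate 3 to 2.43 without replicate 2. The cause was not tested.

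Leaving out each library in turn gave ranges of genes called against control of 608 (without 4 h replicate 2) to 1954, 4202 to 5213, 1827 (without 12 h replicate 1) to 3046, 4107 to 5048, 3928 to 4958, 4468 to 5042 and 368 (without 48 h replicate 1) to 2732 (without replicate 4). Successive pairs ranged from 1610 to 3536, 135 to 1895, 567 to 1788, 65 to 131, 98 to 310 and 1048 to 2442, the times from 6063 to 6763 and the slope from 1753 to 2902. Lists called from 16 to 20 h ranged from 6 to 14, genes changed at all times from 61 to 428 and genes highest at 12 h from 176 to 591. Of the named genes' calls in these refits 442 were lost, 119 gained and 13949 unchanged.

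The replicate number as a block, with controls 1 to 4, gave 1631, 4469, 2606, 4063, 4238, 4455 and 1801 genes from 4 to 48 h, against 1747, 4484, 2626, 4084, 4247, 4464 and 1778 without the block on the same libraries. The numbers do not pair the libraries: deviations from the group means correlated at a mean of 0.0248 for the same number (-0.594 to 0.571) and -0.00623 for other numbers, and 12 of 32 libraries correlated best with their own number.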

Other observations

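The comparison of clock genes at 24 and 48 h was chosen only after the result was seen. The test of library sets for it was stated before, but with sets defined after the data were seen.

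Of the cell cycle list, MCM2, MCM3 and MCM4, which load onto DNA before replication, had risen by 16 h (2.57, 1.84 and 2.23; the first 2 not called against the 2 controls of their set, edgeR adjusted p = 0.0539 and 0.0831) and stayed high at 20 h (3.00, 2.38 and 2.51), while TOP2A, needed at mitosis, was -0.37 at 16 h (edgeR adjusted p = 0.602) and -0.57 at 20 h (0.429) and rose at 24 h (1.35) and 48 h (3.19); the difference between them was not tested. Transcripts of the muscle ubiquitin ligase genes TRIM63 and FBXO32 rose to 4518 ± 1151 and 1319 ± 229 CPM at 16 h from 436 ± 110.1 and 319 ± 110.3 in the controls, and at 48 h TRIM63 was still higher (0.98), though not against controls of its set (edgeR adjusted p = 0.0922), and FBXO32 was 0.48 (edgeR adjusted p = 0.212).

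Clock genes differed among the times: 12 of 18 in the table passed. A candidate explanation is the time of day of sampling, which the labels do not give. Over clock genes, the means at 24 and 48 h, a day apart, as deviations from the mean of all times, correlated at 0.478. Those at 8 and 20 h gave -0.695, but no other pair 12 h apart on the clock was tested. Genes are not independent replicates. With the library sets as a term 8 genes passed, so the sets cannot be told apart from time of day as a contribution to the rest. Injury itself, which also differs in age between the times, stays open.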
